A study of Homo sapiens with 3 samples.

How the data were processed

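Chromatin of MDA-MB-231 LM2 cells was sonicated and immunoprecipitated, per the labels' protocols, from 30 µg of chromatin with 4 µg of an antibody to H3.1 and H3.2 or 6 µg of an antibody to H3.3, and sequenced with input DNA as 75 nt single-end reads on an Illumina NextSeq 500. The samples were 1 H3.1/H3.2 ChIP, 1 H3.3 ChIP and 1 input DNA, grouped by their titles. BWA and SICER and the hg38 build are named, per the submitters' processing notes, and their versions and settings are not given in the sources used here. Whether the input served as control of the region calls is not given there either.

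The authors deposited 1 table of merged regions, which holds, per the file headers, a pileup signal of each ChIP library, given as the mean and the highest height over each region. Regions called in either ChIP were merged into 1 list with a mark for each ChIP that was called, per the file headers. The authors also gave a log2 ratio of H3.3 over H3.1/H3.2, per the file headers, which equalled the ratio of both mean heights without a pseudocount to within 8.9e-16. In 43 regions with a height of 0 the deposited ratio was not a number. How the libraries were scaled to each other before the signal was deposited by the authors is not given in the sources used here, so the sign of a log2 ratio holds relative to that scaling. The headers of the ChIP columns also carry a tag for a hairpin against GFP that no sample label names, so whether the cells carried one is not settled. Enrichment over input had been planned, but the input was not analysed here.

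Region starts and ends are printed as deposited, in steps of 200 bases, with no statement on whether the first base is counted from 0 or 1. CpG islands, promoters and assigned genes were the authors' annotation, per the file headers. A promoter window of 7500 bases upstream to 2500 bases downstream of a gene's start was recovered from the table, and it gave the authors' promoter mark in 100% of 36810 regions with a single gene. A region was placed at a promoter where the authors counted one, otherwise in a gene body if inside a gene, near a gene if another gene was assigned, and away from genes if none was. Of 21948 gene symbols in the table, 17809 were found in the RefSeq gene table used for gene classes and older symbols, and CYR61 and CTGF stood for CCN1 and CCN2.

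All values below were computed from the mean heights as log2((H3.3 + 1)/(H3.1/H3.2 + 1)), with a pseudocount of 1, over chromosomes 1 to 22 and X. The pseudocount understates the ratio of low regions. Folds of single genes are plain ratios of mean heights. The number of tags in a region was taken as mean height times length divided by 224, the constant by which the table itself relates heights to tags. Folds carry exact conditional 95% intervals and heights exact Poisson 95% intervals on these tags, and because reads had no molecular identifiers these cover counting error only. If the heights had been scaled, the tags and their intervals would be off by the same factor. Shares carry exact Clopper-Pearson 95% intervals. Medians carry exact binomial order-statistic 95% intervals over regions or genes, given for 6 or more values, and a difference of medians combines the widths of both intervals in quadrature.

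A gene's promoter value was that of the region in the promoter window nearest its start, and its body value the median of regions inside the gene outside that window. A total of 25 gene lists, 21 by name and 4 by symbol, were compared with 10000 random lists of as many genes drawn from the same 10 bins of mean height, and the percentile of a list's median describes these libraries. Neighbouring genes can share a region, and their values are then the same measurement. The region nearest a gene's start can still lie several kb from it and be assigned to neighbouring genes too. Such distances are given below for some genes only. The lists, the main definitions, the first group of alternatives and the rule for named genes were set before the data were examined. That rule names every EMT transcription factor with a promoter region, the 2 highest and 2 lowest members of each other list, the 10 highest and 10 lowest promoter regions among those at or above the median height, and the 5 longest regions called in each ChIP alone, leaving out Y-linked genes and XIST. Some genes that the rule selects are not reported here, and they remain in the counts, medians and percentiles.

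Alternatives were pseudocounts of 10 and 0.1, peak in place of mean heights, regions of at least 1000 bases, regions above a minimum height, shares of bases, stricter calls, the mean over all regions of a gene and a window of 1000 bases around the start. Others were added after the data were seen. They were a centring on regions called in both, only regions called in both, only regions without a CpG island, random lists matched on CpG islands, and 1 value per region. The list comparison was tested on simulated data over 17529 genes, where 3 of 100 unshifted lists of 20 genes, 73 of 100 lists shifted by 0.5 and 99 of 100 shifted by 1 on the log2 scale exceeded percentile 97.5. The simulated lists drew genes at random with ratios shuffled within bins of height. They therefore lack the shared and neighbouring regions of clustered lists, for which these rates may not hold. Intervals of medians and folds covered the simulated truth in 95.5% and 96.0% of 2000 simulations. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.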

Results

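MDA-MB-231 LM2 cells, a lung-tropic and highly metastatic derivative of the human triple-negative breast cancer line MDA-MB-231, were profiled for the genomic distribution of histone H3 variants by chromatin immunoprecipitation and sequencing (ChIP-seq). H3.1 and H3.2 are the canonical forms, deposited mainly during DNA replication by the CAF-1 chaperone, and H3.3 is the replacement form, deposited throughout the cell cycle by the HIRA and DAXX-ATRX chaperones. One antibody recognised H3.1 and H3.2 together and another recognised H3.3. The series holds 3 samples, 1 H3.1/H3.2 ChIP, 1 H3.3 ChIP and 1 input DNA. Values of both ChIP libraries over merged regions were analysed, and the input was not analysed here. With 1 library per antibody there was no replicate check, so no p-value is given and all intervals cover counting error, or the spread over regions, only.

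The merged list comprised 67969 regions on hg38, of which 4 on chromosome Y were left out. The remaining 67965 regions spanned 176.9 Mb with a median length of 1799 bases. An estimated 5897938 tags of the H3.1/H3.2 library and 7332517 of the H3.3 library fell in these regions, a median of 45.03 and 56.08 tags per region, and the depth of the whole libraries is unknown. The median pileup height was 6.62 for H3.1/H3.2 and 7.76 for H3.3. At this depth the 95% counting interval of the H3.3 over H3.1/H3.2 fold lay above 1 in 30740 regions (45.2%), below 1 in 22975 (33.8%) and included 1 in 14250 (21.0%).

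The first comparison asked how far both kinds of H3 marked the same regions of the metastatic line. Most regions were called in a single ChIP. H3.3 alone was called in 31080 regions (45.7%, 95% exact binomial interval 45.4 to 46.1), H3.1/H3.2 alone in 25824 (37.996%, 37.63 to 38.36), and both in 11061 (16.3%, 16.0 to 16.6). Regions called in both were longer, with a median of 3999 bases against 1799 for H3.3 alone and 1399 for H3.1/H3.2 alone, and so held 35.4% of the bases. A CpG island lay in 43.9% of regions called in both, in 29.5% of those called in H3.3 alone and in 4.73% of those called in H3.1/H3.2 alone. Merging joins calls of both ChIPs, and a longer region can more easily hold a call of each and a CpG island. The length, share of bases and CpG island share of regions called in both may therefore partly reflect the merging. The median log2 ratio of H3.3 over H3.1/H3.2 was 0.27 (0.24 to 0.29) over all regions, 1.24 in H3.3-only regions, -0.93 in H3.1/H3.2-only regions and 0.02 in regions called in both. How the libraries were scaled to each other is not given in the sources used here, and the sign of every ratio holds relative to that scaling.

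The heights of both libraries were negatively correlated across all regions (Spearman's rho -0.39, across regions, which are not independent replicates), but positively within each kind of call, at 0.12 for both, 0.28 for H3.3 alone and 0.43 for H3.1/H3.2 alone. A region entered the list only if called in at least 1 ChIP. With peak heights in place of mean heights the correlation over all regions was -0.034.

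The next comparison addressed the place of each variant relative to genes. Counted by region, H3.3 was the higher at gene starts and at sites away from genes, and H3.1/H3.2 along gene bodies. The median log2 ratio was 0.78 (0.77 to 0.80) in 23465 promoter regions, -0.48 (-0.50 to -0.47) in 37405 gene body regions, 1.07 in 3249 regions near a gene and 1.31 (1.29 to 1.33) in 3846 regions away from genes. Promoter regions exceeded gene body regions by 1.26 (1.24 to 1.28) on the log2 scale and were below regions away from genes, with a difference of -0.53 (-0.55 to -0.50). Of the H3.1/H3.2-only regions 77.9% lay in gene bodies and 18.1% (17.6 to 18.5) at promoters, whereas 42.7% (42.1 to 43.2) of H3.3-only regions lay at promoters, 39.0% in gene bodies and 10.6% away from genes. Among regions called in both ChIPs, promoters exceeded gene bodies by 0.22 (0.20 to 0.25), and the difference from regions away from genes was -0.12 (-0.30 to 0.06), which included 0.

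**Figure D1:**
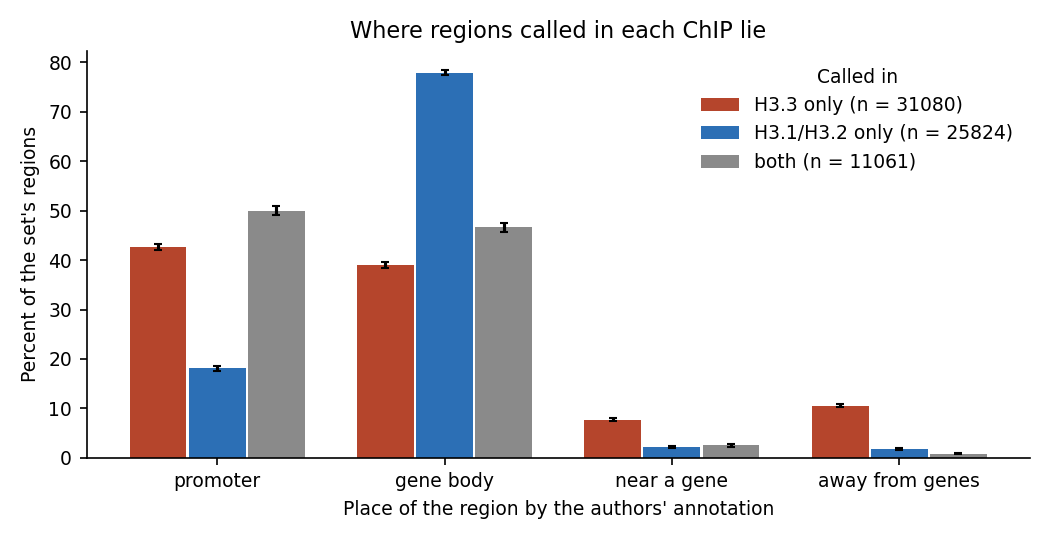
Percent of regions at promoters, in gene bodies, near a gene and away from genes (horizontal axis), for regions called in H3.3 only, in H3.1/H3.2 only and in both ChIPs. Bars are shares of each set with 95% exact binomial intervals; 77.9% of H3.1/H3.2-only regions lay in gene bodies, against 39.0% of H3.3-only regions.

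Along genes the profiles crossed. The median H3.3 height was 8.52 in regions centred 10000 to 5000 bases upstream of a gene's start, 10.9 (10.74 to 11.02) within the first 500 bases of the gene, 7.75 between 3000 and 5000 bases and 5.95 (5.86 to 6.05) between 20000 and 50000 bases. H3.1/H3.2 had its lowest median, 4.94 (4.85 to 5.04), in the 1000 bases upstream of the start and 7.55 (7.48 to 7.61) between 10000 and 20000 bases into the gene. In regions more than 200000 bases into a gene H3.3 was again the higher, at 7.55 against 6.00. Counted once per gene, the gene body median over 10592 genes was 0.11 (0.06 to 0.17), on the H3.3 side of 0 and opposite in sign to the median over regions. Within single genes, 8111 had both a promoter and a gene body region, and the promoter log2 ratio exceeded that of the body in 71.2% of them, with a median difference of 0.49 (0.46 to 0.52). The promoter was above 0 and the body below 0 in 2785 of these genes, and the opposite held in 468.

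**Figure D2:**
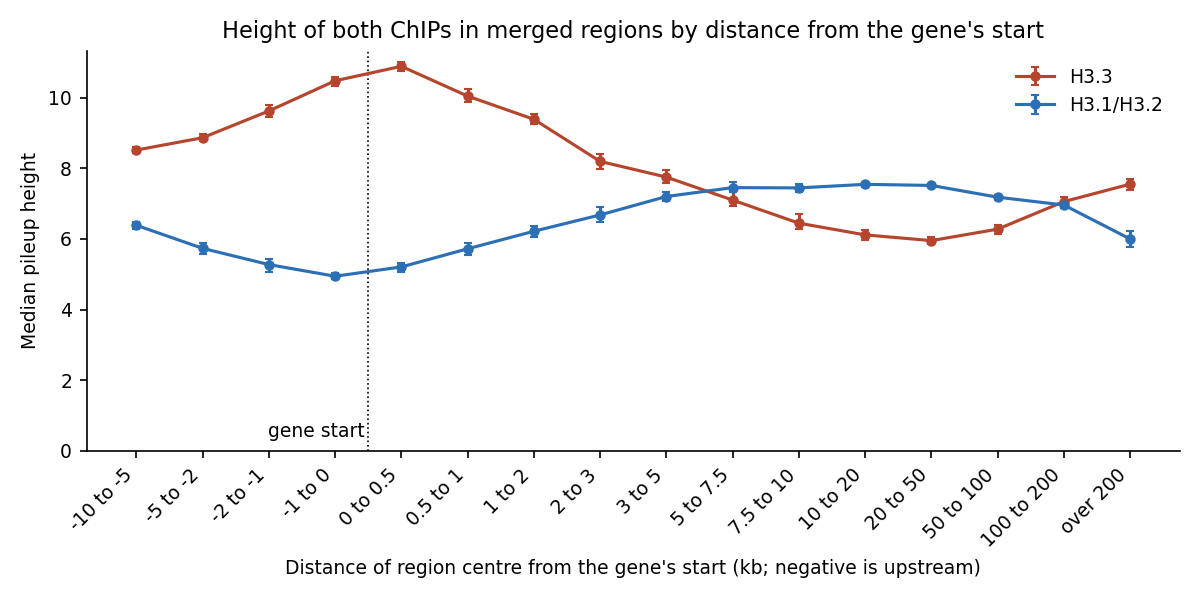
Median pileup height of H3.3 and H3.1/H3.2 (vertical axis) in regions binned by the distance of their centre from the start of an assigned gene in kb (horizontal axis). Points are medians over pairs of a region and a gene with 95% intervals; H3.3 is highest, at 10.9, in the first 500 bases of genes and H3.1/H3.2 is lowest, at 4.94, just upstream of the start.

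CpG islands followed H3.3. The 15240 regions with a CpG island had a median log2 ratio of 0.92 (0.90 to 0.93) and the 52725 without one had -0.22 (-0.24 to -0.20), a difference of 1.14 (1.11 to 1.17). Of the regions with an island 60.2% were called in H3.3 alone and 8.01% in H3.1/H3.2 alone. Among regions with an island, promoters exceeded gene bodies by 0.13 (0.07 to 0.19), and among those without one by 1.12 (1.08 to 1.16).

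Chromosomes differed in the balance of both kinds of H3. The median log2 ratio was highest on chromosomes 22 (0.75, 0.69 to 0.82) and 21 (0.67, 0.50 to 0.80) and lowest on chromosomes 5 (-0.28, -0.35 to -0.20) and 4 (-0.26, -0.38 to -0.14). On chromosome 19, which carries most of the large zinc finger gene clusters, the promoter median of 0.53 was the lowest of all chromosomes. Chromosomes 22 and 21 were the only ones with a gene body median above 0, at 0.23 and 0.09.

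At the level of genes, 17529 genes had a promoter region, with a median log2 ratio of 0.89 per gene. Among promoter regions at or above the median height, the 10 with the largest H3.3 excess included the region shared by the zinc finger gene ZNF641 and LOC105369754 (chromosome 12, 48350000 to 48350799; 17.3-fold, 6.64 to 66.9, from 71 and 4 tags). They also included FSCN2, which encodes a retinal actin-bundling protein, in a region also assigned to the cytoskeletal actin gene ACTG1 and to LOC105371928 (11.7-fold, 7.60 to 18.7). Others among them lay at RNPS1, a splicing and exon junction factor, with its neighbour ABCA3 and 3 microRNA genes (11.2-fold), CDC7, the kinase that fires replication origins, with LOC105378856 (10.8-fold), ZBTB1, a transcription factor of lymphoid development, with its neighbour ZBTB25 and LOC102723809 (10.2-fold), LAMC1, a laminin chain of basement membranes (11.1-fold, 6.10 to 20.7), RFX3, a regulator of ciliary genes (9.49-fold), TMBIM4 (10.1-fold) and FGFR3, a fibroblast growth factor receptor (11.5-fold, 5.85 to 28.6).

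Of the 10 promoter regions at the other end, 4 lay at the zinc finger genes ZNF134 (0.259-fold, 0.213 to 0.315), ZNF268 (0.268-fold, 0.214 to 0.332), ZNF316 (0.296-fold, 0.266 to 0.328) and ZNF43 (0.288-fold, 0.241 to 0.346). In ZNF316 the region, called in both ChIPs, ran over 15199 bases (chromosome 7, 6637800 to 6652999) with mean heights of 22.98 for H3.1/H3.2 and 6.80 for H3.3. NDUFAB1, the mitochondrial acyl carrier protein, was at 0.265-fold (0.188 to 0.364) and TCTN3, a protein of the ciliary transition zone, at 0.284-fold (0.195 to 0.402). The remaining regions lay at the microRNA genes MIR6724-4 (0.156-fold, 0.0462 to 0.391) and MIR6501, in a region also assigned to GART and SON (0.287-fold), the tRNA gene TRC-GCA20-1 (0.269-fold, 0.0869 to 0.659) and LOC105372306, in a region also assigned to ZNF506 (0.255-fold). Neighbouring genes assigned to these regions were named after their values were seen, and not each of them is named.

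Long single-variant regions sat mostly inside genes. The longest H3.3-only region spanned 35599 bases (chromosome 19, 929800 to 965399), with mean heights of 15.5 for H3.3 and 3.01 for H3.1/H3.2. It lay inside ARID3A and downstream of KISS1R, the receptor of the metastasis suppressor kisspeptin. The next lay in ZCCHC24, in COL18A1, which encodes the basement membrane collagen that gives rise to endostatin, and in ZMIZ1, with log2 ratios of 1.07, 1.57 and 1.33. The longest H3.1/H3.2-only region, 23599 bases on chromosome 21 (7934800 to 7958399), had no gene assigned and a log2 ratio of -1.99. It was followed by regions in ZMYND8, a chromatin reader (chromosome 20, 47235200 to 47255399, -0.73), in CDCA7L (-1.14), in PPP2R1A, a scaffold subunit of protein phosphatase 2A (-1.68), and in ZNF146 (-1.34).

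The series ties H3 variants to aggressive traits, which gene lists were used to describe. Transcription factors of the epithelial-mesenchymal transition (EMT), the programme by which epithelial cells become motile, leaned to H3.3 at most of their promoters. Of 14 such factors with a promoter region, 11 were called in H3.3 alone, 2 in both, among them SOX9, and FOXC2 in H3.1/H3.2 alone, and the counting interval of the fold lay above 1 in 13. Promoter regions in general leaned the same way, with 56.6% called in H3.3 alone. Among genes typical of other cells, the fold interval lay above 1 at 6 of 6 immune cell markers and 5 of 5 fibroblast and endothelial markers. It did so at 8 of 9 liver, pancreas, muscle, erythroid and retina genes and at 6 of 8 neuronal genes. High counts are therefore not particular to the EMT list or the lists that follow, and the share over all promoters is not given here. TCF3 had the highest ratio (4.39-fold, 3.499 to 5.497, chromosome 19, 1652800 to 1660199), followed by ZEB1, a repressor of epithelial genes (4.07-fold, 2.79 to 6.14, chromosome 10, 31317800 to 31319799, covering the start), SNAI3 (3.89-fold, 2.06 to 7.72), FOXQ1 (3.84-fold, 2.79 to 5.41) and SOX4 (3.51-fold, 2.40 to 5.17). The E-cadherin repressors SNAI1 (2.86-fold, 2.18 to 3.74, chromosome 20, 49979200 to 49982599) and SNAI2 (2.68-fold, 1.40 to 5.08), the Wnt effector LEF1 (3.35-fold, 2.22 to 5.24) and FOXC1 (2.83-fold, 1.86 to 4.35) came next. SOX2 (2.10-fold), PRRX1 (1.68-fold, 1.09 to 2.64) and SOX9 (1.49-fold, 1.13 to 1.95) were nearer to balance, and at FOXC2 the ratio was 0.682-fold (0.345 to 1.31). TWIST2, ETS1 and RUNX2 had no promoter region, and the other 5 of the 22 listed factors had no region assigned under the symbols searched.

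The EMT factors' median log2 ratio of 1.30 (0.52 to 1.75) stood at percentile 96.4 of 10000 random gene lists of the same size and height, a description of these libraries and not a test. Restricted to regions of at least 1000 bases the percentile was 98.2, and with peak heights it was 67.7.

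**Figure D3:**
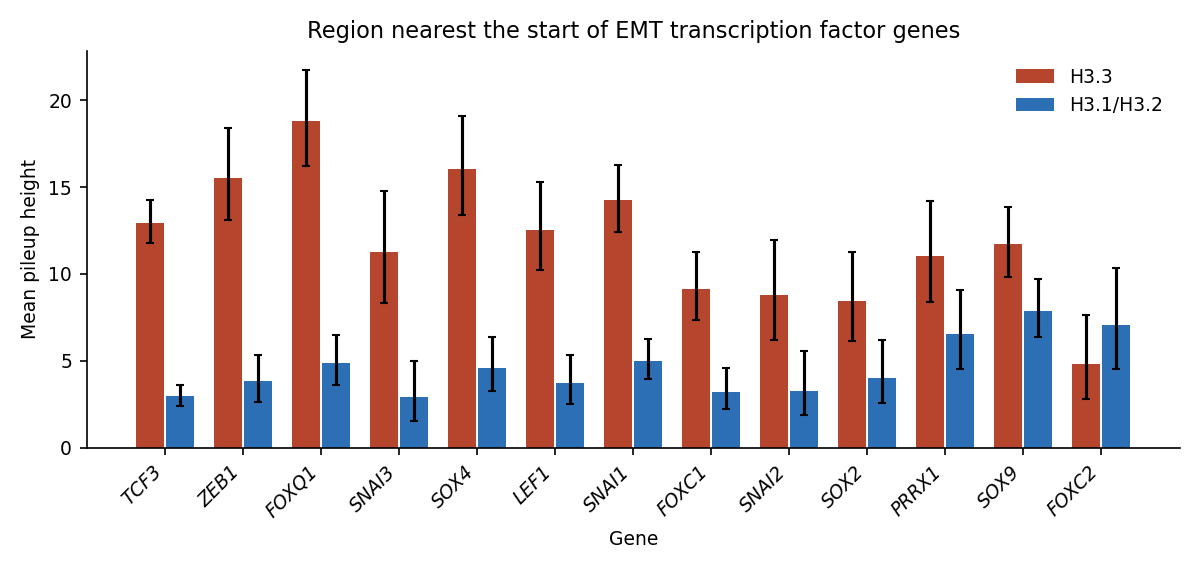
Mean pileup height (vertical axis) of H3.3 and H3.1/H3.2 in the region nearest the start of the EMT transcription factor genes named in the text (horizontal axis), in order of the log2 ratio. Bars are the single libraries' values and error bars 95% Poisson intervals for counting error; H3.3 exceeds H3.1/H3.2 in 12 of the 13 genes shown and FOXC2 is the exception.

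Mesenchymal and epithelial genes both stood on the H3.3 side. Of 24 mesenchymal effectors, 19 were called in H3.3 alone, 4 in both and ITGB1 in H3.1/H3.2 alone, with a median log2 ratio of 1.30 (0.74 to 1.71, percentile 98.9). The matrix protein tenascin C, TNC (7.63-fold, 4.60 to 13.5, chromosome 9, 115117800 to 115119399), and CYR61, a secreted matricellular protein (5.94-fold, 4.49 to 7.87), were the highest, and the integrin subunit ITGB1 (0.573-fold, 0.384 to 0.852) and SPARC (0.872-fold, 0.643 to 1.17) the lowest. Of 25 epithelial genes, 20 were called in H3.3 alone and the fold interval lay above 1 in 24, with a median of 1.43 (1.39 to 1.51, percentile 99.3). The membrane protease gene ST14, encoding matriptase (6.96-fold, 3.48 to 14.8), and OVOL1, an epithelial transcription factor (4.91-fold, 3.34 to 7.42), were the highest. The lowest were MARVELD2, a tight junction protein (0.517-fold, 0.333 to 0.810), and the protease PRSS8 (1.75-fold, 1.28 to 2.42). Their regions lay 2113.5 and 4169.5 bases from the starts of MARVELD2 and PRSS8 and were also assigned to neighbouring genes. With peak heights the percentile was 92.1 for the epithelial list, and the lowest for the mesenchymal list over the alternatives was 92.4.

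Genes of the TGF-beta pathway, an inducer of EMT, and genes of the lung metastasis signature known for the parental line also leaned to H3.3. All 18 TGF-beta genes with a promoter region had a fold interval above 1, with a median log2 ratio of 1.42 (0.97 to 1.81, percentile 99.7, or 92.0 with peak heights). That count was also full for 6 immune cell markers and 5 fibroblast and endothelial markers, and was 6 of 8 for neuronal genes. The pathway's inhibitor SMAD7 (6.07-fold, 2.48 to 21.0) and effector SMAD3 (5.37-fold, 3.51 to 8.23) were the highest and the receptor TGFBR2 (1.54-fold, 1.05 to 2.29) and SKIL (1.62-fold, 1.03 to 2.66) the lowest. In the lung metastasis signature 9 of 11 genes were called in H3.3 alone, with a median of 1.51 (0.40 to 1.88, percentile 98.8, or 90.6 over all regions of each gene). TNC and ANGPTL4, which loosens lung capillary junctions (4.39-fold, 3.297 to 5.814), were the highest, and SPARC and MAN1A1 (1.39-fold, 0.638 to 3.25) the lowest.

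Other breast cancer lists were less distinct from random lists. The 8 luminal and hormone receptor genes had a median of 0.76 (-0.57 to 1.86, percentile 29.9) and split widely. The pioneer factor FOXA1 (4.88-fold, 1.90 to 13.8) and the receptor ERBB2 (3.43-fold, 2.40 to 4.89) leaned to H3.3, whereas GATA3, the luminal master regulator, was called in H3.1/H3.2 alone (0.638-fold, 0.517 to 0.789) and MLPH in both (1.43-fold). Within 1000 bases of the start, which left 6 genes, the median was 1.26 (percentile 84.0). The 11 basal and stemness genes all had a fold interval above 1, with a median of 1.34 (0.99 to 1.95, percentile 92.7, or 94.9 with peak heights). Over the alternatives the percentile ran from 83.7, within 1000 bases of the start, to 96.5, over all regions of each gene. ALDH1A3, a stem cell marker enzyme (5.09-fold, 3.51 to 7.78), and NOTCH3 (4.65-fold, 3.18 to 7.10) were the highest, and ITGB4 (1.99-fold, 1.75 to 2.28) and the Polycomb subunit BMI1 (2.12-fold) the lowest. The BMI1 region lay 4011.5 bases from the gene's start and was also assigned to neighbouring genes.

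Signal-responsive genes followed the same direction. The 21 AP-1 and immediate early genes had a median log2 ratio of 1.20 (0.82 to 1.48, percentile 97.3), with the MAP kinase phosphatase DUSP6 (4.995-fold, 3.77 to 6.60) and ATF3 (4.44-fold, 2.49 to 8.70) highest and KLF4 (1.25-fold, 0.964 to 1.63) and KLF2 (0.497-fold, 0.219 to 1.19, from 10 and 19 tags) lowest. The 15 NF-kB and inflammatory genes had a median of 1.25 (1.04 to 1.66, percentile 92.3). Among them the cytokine genes IL11 (6.39-fold, 3.16 to 13.6) and LIF (5.32-fold, 3.58 to 8.25) were highest, and IL1A (1.65-fold, 0.959 to 2.90) and RELB (0.869-fold, 0.508 to 1.44) lowest. The IL1A region lay 5205.5 bases from the gene's start. The 18 hypoxia and glycolysis genes had a median of 1.18 (0.64 to 1.54, percentile 97.3). PGK1, a glycolytic kinase, reached an H3.3 height of 67.3 against 10.8 for H3.1/H3.2 (6.22-fold, 4.90 to 8.05, chromosome X, 78103200 to 78104799), ENO1 was at 4.71-fold, and SLC2A3 (1.04-fold) and PFKFB4 (1.24-fold, 1.19 to 1.30), which shares a region of 61799 bases with its neighbours, were the lowest. Over all regions of each gene the percentiles of these lists were 100 for AP-1, 98.8 for NF-kB and 91.7 for hypoxia genes, and with a pseudocount of 10 it was 98.9 for hypoxia genes.

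Among genes that dividing cells use widely, proliferation genes had a lower median than ribosomal protein and housekeeping genes, with overlapping intervals, and the difference between lists was not tested. The 23 proliferation and DNA replication genes had a median of 0.37 (-0.11 to 0.71, percentile 3.445), with 12 called in both and 10 with a fold interval above 1. The mitotic cyclin gene CCNB1 (0.553-fold, 0.450 to 0.674, chromosome 5, 69166600 to 69171599) was among the lowest, and the checkpoint kinase BUB1 (4.30-fold, 2.42 to 8.88) and TYMS (3.28-fold, 1.49 to 8.60) the highest. The 32 ribosomal protein genes had a median of 1.09 (0.63 to 1.32, percentile 99.8), with 24 called in both, from RPL3 (5.44-fold, 3.90 to 7.69) and RPS18 (3.39-fold, 2.75 to 4.18) to RPL22 (0.745-fold, 0.563 to 0.981). The 18 housekeeping genes had a median of 1.08 (0.47 to 1.26, percentile 96.6), with the elongation factor EEF1A1 (4.16-fold, 3.31 to 5.29) and YWHAZ (3.58-fold) highest and the transferrin receptor TFRC (0.756-fold, 0.606 to 0.940) and TBP (0.682-fold, 0.537 to 0.868) lowest. The proliferation percentile was 2.15 when random lists were also matched on CpG islands and 31.8, with a median of 0.71, with peak heights. The ribosomal percentile was 92.9 over all regions of each gene, and the housekeeping percentile 98.6 in regions of at least 1000 bases.

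The genes of the H3 deposition machinery itself were mixed. The 12 chaperone and H3.3 genes had a median of 0.51 (0.24 to 1.15, percentile 36.7), with 7 called in both. H3F3A, which encodes H3.3 (4.83-fold, 3.08 to 8.16, chromosome 1, 226062600 to 226063999), and UBN2 of the HIRA complex (2.85-fold, 1.81 to 4.51) were highest. HIRA (0.883-fold, 0.551 to 1.40) and CHAF1A, a CAF-1 subunit (0.942-fold, 0.670 to 1.33), had intervals that included 1. Over all regions of each gene the list's median was 0.021 (percentile 6.58).

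Lists of genes typical of other tissues or of development had few promoter regions. The 15 HOX genes, body axis regulators, shared 11 regions and had a median of 0.96 (0.54 to 1.23, percentile 25.2), from HOXB2 (6.95-fold, 1.86 to 33.4) and HOXC9 (3.39-fold) to HOXB3 and HOXB5, which share 1 region (1.04-fold, 0.738 to 1.48). Above the lower quartile of height the HOX median was 0.56 (percentile 3.79) over 14 genes, whereas over all regions of each gene the percentile was 85.6. For 5 other developmental regulators the median was 1.02 (percentile 31.8), with TBX1 (4.85-fold) and PAX8 (3.98-fold) highest and NKX2-5 (1.78-fold) and GATA6 (2.08-fold) lowest, and above the lower quartile of height, which left 3 genes, the median was 1.65 (percentile 90.7). The 9 liver, pancreas, muscle, erythroid and retina genes had a median of 1.39 (0.85 to 1.63, percentile 82.4), with CPA1 (3.83-fold) and the insulin gene INS (3.95-fold, 3.18 to 4.98) highest and OPN1SW (1.99-fold) and APOA2 (0.463-fold, 0.318 to 0.678) lowest. The regions of CPA1 and APOA2 lay 5572.5 and 2571.5 bases from their starts and were also assigned to neighbouring genes. The 8 neuronal genes had a median of 0.92 (-1.163 to 1.964, percentile 37.7), between the glutamate receptor subunits GRIN1 (4.91-fold, 3.51 to 7.07) and GRIN2A (0.387-fold, 0.212 to 0.656), with DLG2 at 1.27-fold. Within 1000 bases of the start, which left 5 neuronal genes, the median was 1.64 (percentile 96.7). The medians were 1.24 (percentile 79.2) for 6 immune cell markers, with CSF1R (3.04-fold) among the highest and SPI1 (2.24-fold) and CD8A (1.82-fold) lowest, and 1.31 (percentile 64.9) for 5 fibroblast and endothelial markers, from CLDN5 (3.49-fold) and PDGFRB (3.41-fold) to PECAM1 (2.12-fold) and RGS5 (1.99-fold). The PECAM1 region lay 6798.5 bases from the gene's start. Only SYCP3 (0.473-fold, 0.295 to 0.751) and TDRD1 (1.32-fold, 0.900 to 1.95) of the germ line list had a promoter region, with a median of -0.29 (percentile 6.95).

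Among lists of at least 6 genes, zinc finger genes and clustered protocadherins had the lowest medians, and olfactory receptor and histone genes the highest. Replication-dependent histone genes, which supply canonical histones in S phase, leaned strongly to H3.3, with a median of 1.70 (1.53 to 1.78, percentile 100) over 41 genes in 27 regions, 37 of the genes being called in H3.3 alone. HIST2H3D and HIST2H2BF, which share a region of 199 bases (10.5-fold, 2.31 to 631, from 15 and 1 tags), were highest, and HIST2H3A and HIST2H2AA4 (0.375-fold, 0.221 to 0.629) lowest. The region of HIST2H3A and HIST2H2AA4 lay 4620.5 and 3062.5 bases from their starts and was also assigned to neighbouring genes. C2H2 zinc finger genes, many of which encode repressors of transposable elements, had a lower median of 0.23 (0.06 to 0.50, percentile 0) over 394 genes. They ranged from ZNF641 and ZNF521 (8.08-fold, 1.34 to 55.2) to ZNF155 (0.155-fold, 0.0437 to 0.366) and ZNF257 (0.108-fold, 0.0312 to 0.341). The ZNF257 region lay 4733.5 bases from the gene's start. Clustered protocadherins, neuronal adhesion proteins encoded on chromosome 5, had a median of -0.9996 (-1.09 to -0.30, percentile 0) over 15 genes in 11 regions, 14 of the genes being called in H3.1/H3.2 alone. The fold interval lay below 1 in 9 of these genes and included 1 in 6. Because these genes neighbour each other and random lists drew genes from all chromosomes, the interval and percentile may largely describe a single locus. Many histone genes neighbour each other too, so their interval and percentile may describe a few loci. PCDHGB3 (0.357-fold, 0.256 to 0.486) and PCDHGA6 (0.377-fold, 0.277 to 0.520) were lowest and PCDHGC3 and PCDHGC4, which share 1 region (0.875-fold, 0.659 to 1.16), highest. The shared region lay 6375.5 bases from the start of PCDHGC4. The 6 olfactory receptor genes had a median of 1.79 (-1.844 to 1.964, percentile 99.6), from OR2AG2 (4.70-fold) and OR2F1 (4.66-fold) to OR2V2 (1.92-fold) and OR4C45 (0.192-fold, 0.0371 to 0.707), but a percentile of 79.5 at the lowest over the alternatives. The OR2F1 region lay 4727.5 bases from the gene's start and was also assigned to neighbouring genes. The OR4C45 region lay 3475.5 bases from the start of OR4C45. With the mean over all regions of each gene the zinc finger median was -0.90 and the protocadherin median 0.0075.

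**Figure D4:**
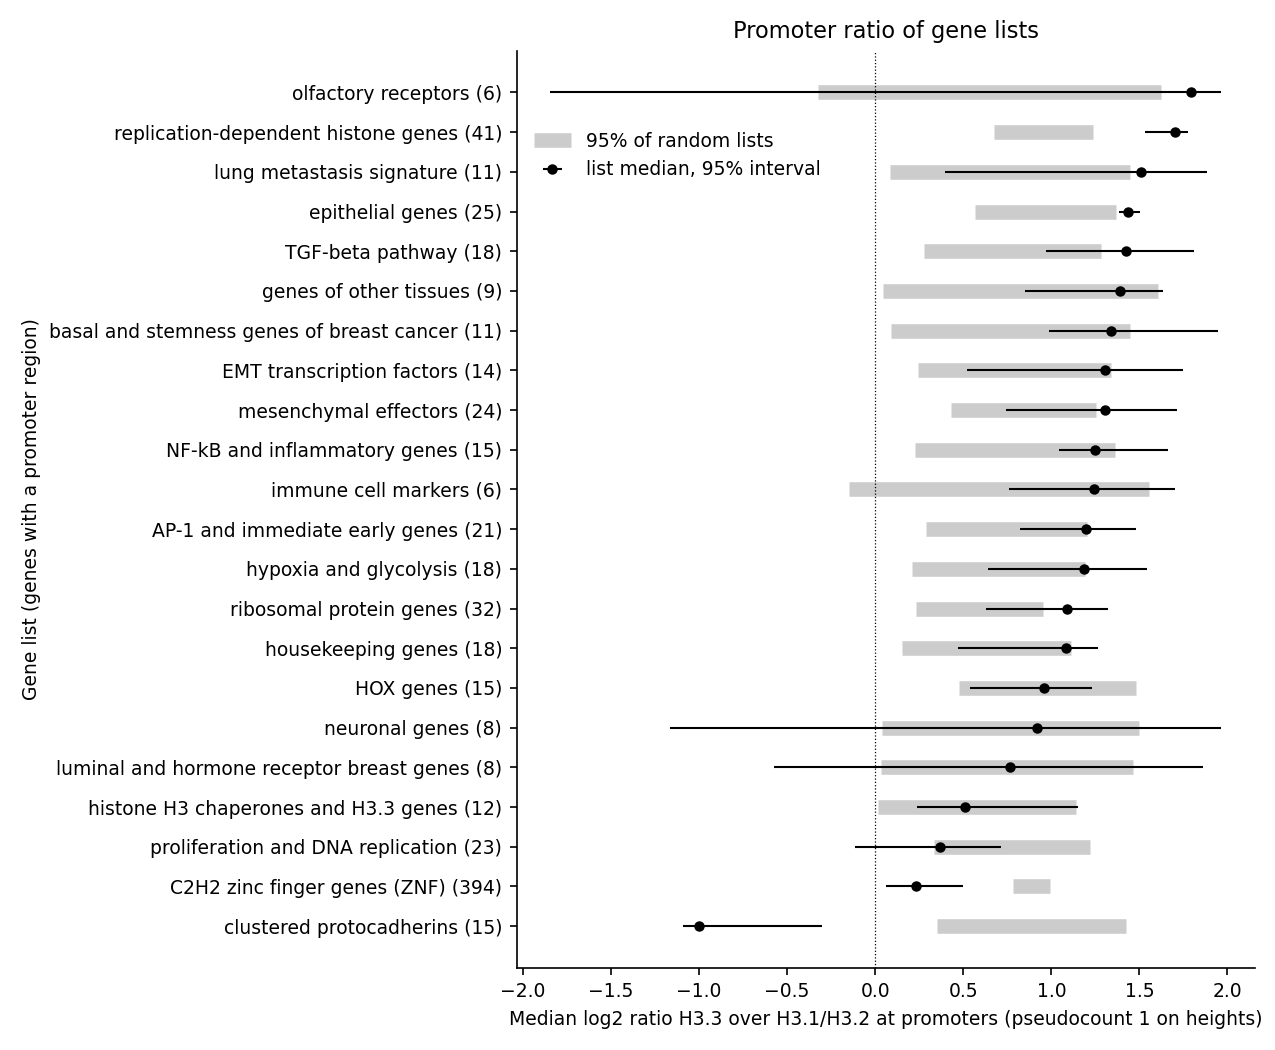
Median log2 ratio of H3.3 over H3.1/H3.2 at promoters (horizontal axis, pseudocount 1) of the 22 gene lists with at least 6 genes (vertical axis, number of genes in parentheses). Points are medians with 95% intervals over genes and grey bars hold 95% of random lists matched on height; histone genes lie above their grey bar at 1.70, zinc finger genes below it at 0.23 and protocadherins below it at -0.9996.

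Gene bodies outside the promoter window gave a partly different order. Zinc finger gene bodies had a median log2 ratio of -1.33 (-1.40 to -1.25, percentile 0) over 373 genes, with 326 below 0. Epithelial gene bodies were at 1.61 (1.23 to 1.81, percentile 100) over 12 genes, each above 0. Smaller lists also lay above the central 95% of random lists, with 1.72 for 5 immune cell markers (percentile 99.7), 1.43 (1.14 to 1.77, percentile 98.7) for 6 fibroblast and endothelial markers and 1.22 (0.62 to 1.52, percentile 99.2) for 6 AP-1 and immediate early genes, each gene above 0. A single gene of the liver, pancreas, muscle, erythroid and retina list had a body region, at 2.44 (percentile 99.9). Bodies of EMT factors (0.75, percentile 80.8, 9 genes), mesenchymal effectors (0.59, percentile 88.7, 19 genes) and TGF-beta genes (0.99, percentile 95.5, 15 genes) lay within the central 95% of random lists, as did those of proliferation genes (-0.31, percentile 9.35, 20 genes) and of chaperone and H3.3 genes (-0.69, -1.03 to 0.47, percentile 3.06, 11 genes).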

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

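Centring, restrictions to regions called in both or without a CpG island, matching on CpG islands and 1 value per region were chosen after the data were seen. Of 259 alternative values, 91 were other pseudocounts, shares or matchings, whose sign or value was largely fixed by construction, 47 left the value as it was and 9 were of lists with no interval. Of the other 112, 89 stayed within the interval of the reported value, 21 moved beyond it with the same sign and 2 changed sign. The latter came from the mean over all regions of each gene, which gave zinc finger genes -0.90 and protocadherins 0.0075; that setting adds gene body regions to the promoter value. Epithelial genes had 1.31 under it. The cause of the other shifts was not tested, except that a larger pseudocount shrinks every ratio by construction.

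The median log2 ratio over all regions was 0.13 with a pseudocount of 10, 0.30 with 0.1, 0.41 above the lower quartile of height, 0.24 with peak heights and 0.35 in regions of at least 1000 bases. In the same order promoters minus gene bodies gave 0.60, 1.42, 1.05, 0.98 and 1.13, promoters minus regions away from genes -0.17, -0.66, -0.57, -0.49 and -0.57, and CpG island minus none 0.55, 1.27, 0.86, 0.93 and 0.92. Promoters minus gene bodies was 0.22 in regions called in both and 1.12 without CpG islands, and promoters minus regions away from genes -0.12 in regions called in both. The share called in both was 29.3% above the median height, 35.4% of bases, 11.4% with stricter calls and 21.1% in regions of at least 1000 bases. Promoters held 49.2% of H3.3-only regions above the median height, and 22.6% of H3.1/H3.2-only regions there and 19.2% in those of at least 1000 bases. Spearman's rho was -0.034 with peak heights and -0.38 in regions of at least 1000 bases.

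With a pseudocount of 10 the promoter medians were 0.63 for mesenchymal, 0.63 for epithelial, 0.62 for TGF-beta, 0.59 for ribosomal protein and 0.77 for histone genes. With 0.1 they were 1.68 for epithelial genes, 1.956 for histone genes and -1.12 for protocadherins. Epithelial genes had 1.18 with peak heights, and zinc finger genes 0.055 in regions of at least 1000 bases. Zinc finger and protocadherin promoters kept percentiles of at most 0.46, and histone promoters 100, under all 9 alternatives. Division by input was not run, and with 1 library per antibody none could be left out. Depth limits single regions: the counting interval of the fold included 1 in 21.0% of regions.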

Other observations

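The grouping by gene class, the regions of greatest height and the test on regions without a CpG island were chosen after the results were seen. Promoters of transcripts that are not translated differed by class. Those of 2096 long non-coding RNA genes had a median log2 ratio of H3.3 over H3.1/H3.2 of 1.10 (1.07 to 1.13, percentile 100 among random lists of the same height), and those of 205 tRNA genes, transcribed by RNA polymerase III and lying in 140 distinct regions, 1.25 (1.12 to 1.36, percentile 100), with 74.6% called in H3.3 alone. Promoters of 852 microRNA genes in 760 distinct regions, many inside other genes, had 0.56 (0.48 to 0.62, percentile 0), and those of 146 pseudogenes 0.52 (-0.18 to 0.76, percentile 0). Those of 41 transcribed pseudogenes had 1.17 (0.71 to 1.46, percentile 87.5), and those of 250 snoRNA genes in 148 distinct regions 0.67 (0.43 to 0.93, percentile 3.69). Intervals and percentiles count a shared region once for each of its genes. The 10679 protein-coding genes had 0.83 (0.81 to 0.85), which also lay below random lists of the same height (percentile 0.605).

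The regions of greatest H3.1/H3.2 height mostly had no gene assigned. The highest lay next to the centromere of chromosome 3 (93470200 to 93470999), with mean heights of 221 for H3.1/H3.2 and 179 for H3.3, followed by chromosome 1 (125183600 to 125184399), at 117 and 83.3. A pair of regions on chromosome 5 (49599400 to 49602999 and 49656400 to 49661999) had 72.5 and 63.8 for H3.1/H3.2 against 30.2 and 31.5 for H3.3, and a region of 12599 bases on chromosome 20 (31057600 to 31070199) 40.7 against 10.9. Repeat content and the placement of reads in such regions were not tested.

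Gene bodies leaned to H3.1/H3.2 relative to promoters, by 1.26 on the log2 scale over regions and by a median of 0.49 within genes, and the tests that follow were made over regions. If the choice of regions called in a single ChIP were the whole source, regions called in both would show no difference, but they showed 0.22 (0.20 to 0.25). That choice was therefore not the whole source. Keeping only regions called in both also removes the regions with large ratios in either direction. The smaller difference therefore does not show how much of the size that choice explains. CpG islands at promoters could not be the whole source either, since the difference was 1.12 (1.08 to 1.16) without them, and neither could length and height, since matching 21606 promoter regions to gene body regions on both left 1.17 (1.14 to 1.19). GC content and the specificity of each antibody were not tested, the antibody cannot be separated from the variant in this design, and the series names no group that would test a biological explanation.

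Zinc finger gene bodies leaned furthest to H3.1/H3.2 among the gene lists. The general gene body trend did not account for this, as their median stood at percentile 0 of random gene bodies of the same height, nor did chromosome 19 as a whole, since 174 such genes on other chromosomes lay below other bodies there, with a difference of -1.04 (-1.25 to -0.84). Reads lost or gained between similar genes would move both libraries the same way. Instead log2 H3.3 height was lower, with a difference of -1.13 (-1.21 to -1.04), and log2 H3.1/H3.2 height higher by 0.30 (0.27 to 0.34). Regions entered the list only if called in at least 1 ChIP, which itself shapes these heights. This comparison therefore cannot exclude an effect of shared reads. A candidate explanation is that these bodies, known in other cells for heterochromatin marks, exchange little H3.3, but no mark or expression was measured here and GC content was not tested.

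Promoters of replication-dependent histone genes leaned to H3.3. Counted once per region, the median over 27 distinct regions was 1.69. It stood at percentile 100 of random promoter regions (95% of which lay between 0.58 and 1.30). Genes that share a single region were therefore not the whole source. Distinct regions can still neighbour each other, and the random regions were drawn from all chromosomes. The count per region therefore cannot exclude an effect of a few loci. The pattern may reflect rapid H3 turnover at strongly transcribed genes, a hypothesis that no test here addressed, and GC content was not tested.

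A further hypothesis held that H3.1/H3.2 in gene bodies follows genes that the line uses. Its test set bodies of ribosomal protein, housekeeping and proliferation genes (35 genes, median -0.10, -0.39 to 0.46) against those of other tissues, neuronal and immune genes (14 genes, median 1.46, 0.68 to 1.79). The difference of -1.56 (-2.25 to -0.86) was in the predicted direction. It came from the lists of other tissues, since the interval of the active lists included 0 and the median of 0.11 over all gene bodies. The difference could arise because genes of other tissues enter only through the few regions called in them. Bodies of 7 ribosomal protein genes, although below those of the other tissues, had a median of 0.64 (0.39 to 1.72), on the H3.3 side of 0. Expression was not measured in these samples.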
